A study of Homo sapiens with 6 samples.

How the data were processed

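RNA immunoprecipitated with Flag-tagged YTHDC1 from HEK293T cells was sequenced in pairs of reads, per the labels, from 2 libraries labelled DMSO and 2 labelled zeocin. The submitters' processing notes name cutadapt 2.8, HISAT2 2.2.0, SAMtools, deepTools 3.4.1, MACS2 2.2.4 and build hg19, without the role or order of each. The authors deposited 1 list per library, so replicates were not pooled. Each list has no header and gives summits of 1 bp with a name and a score. The authors' score is read as −log10 of a p-value or q-value, and which of them is not given in the sources used here. All scores lie above 1.30, the −log10 of 0.05. The threshold and the control of the calls are not given in the sources used here either. Scores were used only to rank, filter and describe summits within a list. Read totals are unknown, and the number of summits does not stand for depth.

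Groups were taken from the sample labels. The peak names in all 4 lists give the other treatment, and this was handled as an alternative. The build was checked against chromosome 1, whose summits reach 249152696, past 248937043, the last annotated gene end there in GRCh38.

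The plan, fixed before the data were examined, assumed whole peaks. Because the lists hold summits, a window of 100 bp on either side (201 bp) stood for each peak, and summits up to 200 bp apart in any lists were joined into a region. Numbers of summits and covered length were compared on the log2 scale with an exact two-sided permutation test over the 6 assignments of the 4 libraries. Regions were counted by the libraries that called them. Sharing was counted for the 6 pairs, in full lists and in the 4171 strongest summits of each list, with ties broken by a fixed random draw. Chance was set by 100 draws in which every summit was moved by 10 to 50 kb, and by 100 random placements on the same chromosome. Shares have 95% Wilson intervals. The rule for named regions took the 10 per pattern with the best worst percentile rank, and a selection of these is named, leaving out those on chromosome X. Gene counts per chromosome came from GENCODE 29 (GRCh38), as did the place of RNA5-8SN2 on a scaffold whose sequence version is the same in both builds.

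The background in the model of the caller was read from the spacing of the scores. Neighbouring score levels followed a Poisson model with a single genome-wide background (R2 from 0.998 to 1.000), whose slope gives that background. On simulated data with known answers the background was recovered to within 1.14%, and 100% of the planted patterns among 179961 simulated regions were recovered. The planted regions lay too far apart to merge, and their summits lay within the joining distance, so full recovery was fixed in advance. It checks the counting only, and closely spaced regions like those of the real lists were not simulated.

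Summits called under one label only were compared with the spacing of exons, which needs no exact position from another build. The list of a library held summits at least 5 score levels above its lowest and more than 1 kb from every summit of the other label. For each of 13571 genes with 8 or more merged exons on the same chromosome, the most exons held by summits under any single offset of up to 3 Mb was counted, with 50 bp added to either end of an exon. Chance was set by 20 draws of displaced summits here. On simulated data, 10 of 10 genes with 50% of their exons planted and 10 of 10 with 90% ranked first. In all, 3 forms of this search were run, all after the data were examined and after the place of the chromosome 8 stretch had raised TG as a possibility. One form searched 6252 genes on all chromosomes, and another used summits at least 2 levels above the lowest. One further result of this search, and a later test that rested on it, are not reported here.

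Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. The alternatives were a score minimum of 5, lists of equal length, each library left out, chromosomes 1 to 22 and X alone, a replicate block, and other overlap and merging distances. Wider windows, strong summits alone, treatment as in the peak names, and lists without the TG stretch were added later. Counts per gene, the planned gene lists, shares of exons and introns, and the DRACH motif need hg19 sequence or annotation and were not analysed here.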

Results

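RNA bound to Flag-tagged YTHDC1, a nuclear protein that binds RNA carrying N6-methyladenosine (m6A), was isolated from HEK293T cells by immunoprecipitation and sequenced. HEK293T is an established line derived from human embryonic kidney. The cells had received the solvent DMSO or zeocin, a drug of the bleomycin family that breaks both strands of DNA. Each treatment had 2 immunoprecipitated libraries with 1 list of peak summits per library. The 2 input libraries, labelled as input DNA, were not analysed here. The series title concerns METTL3, the enzyme that writes m6A, and its part in the repair of DNA breaks by homologous recombination. The comparison therefore asks which RNA YTHDC1 binds when DNA is broken. Summits were not set against an RNA input here, so they may follow the abundance of an RNA as well as its binding. Nothing in the labels says whether the libraries came from separate cultures, so the spread between them may be technical. Positions are 1-based and refer to build hg19.

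The treatment in the sample labels and the treatment in the peak names inside the lists disagreed in all 4 lists. The lists labelled DMSO carried peak names with zeocin and the replicate numbers 1 and 2, and both lists labelled zeocin carried peak names with DMSO and the same replicate number, 1. The lists labelled zeocin were still different lists: 0.127% of the summits of zeocin 1 had the identical position in zeocin 2. Libraries are therefore named by their label (DMSO 1, DMSO 2, zeocin 1 and zeocin 2), and every difference between the treatments given below holds for the labels and would turn if the peak names are right.

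More summits were called in each library labelled zeocin than in each labelled DMSO. Zeocin 1 had 46386 summits and zeocin 2 had 113876, against 4171 in DMSO 1 and 20328 in DMSO 2. The means were 80131 ± 47722.6 (SD, n = 2) and 12249.5 ± 11424.7 (SD, n = 2). The ratio of geometric means was 7.89-fold, a log2 ratio of 2.98, and it was 2.98 for the covered length too, which ran from 838 kb in DMSO 1 to 22889 kb in zeocin 2. Replicates were far apart as well: DMSO 2 had 4.87-fold as many summits as DMSO 1, and zeocin 2 had 2.45-fold as many as zeocin 1. An exact two-sided permutation test over the 6 assignments gave p = 0.333, the smallest p that 2 against 2 libraries allow. Leaving out DMSO 1 lowered the log2 ratio to 1.84 and leaving out zeocin 2 lowered it to 2.33, while it rose to 4.12 without DMSO 2 and to 3.63 without zeocin 1.

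The excess was largest among weak summits. The authors' score of each summit takes few distinct values within a list, and 71.9% of the summits of zeocin 1 and 65.2% of those of zeocin 2 had one of the 2 lowest, against 33.7% in DMSO 1 and 34.3% in DMSO 2. Among summits with a score of 5 or more, zeocin 1 had 5494 and DMSO 2 had 5322, a ratio of 1.03, and the log2 ratio between the groups was 1.46 (exact permutation p = 0.333). Among summits at least 10 score levels above the lowest of their list, called strong here, the numbers were 170 in DMSO 1, 848 in DMSO 2, 276 in zeocin 1 and 1904 in zeocin 2. The groups then overlapped, with a log2 ratio of 0.93 and an exact permutation p of 0.667.

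**Figure D1:**
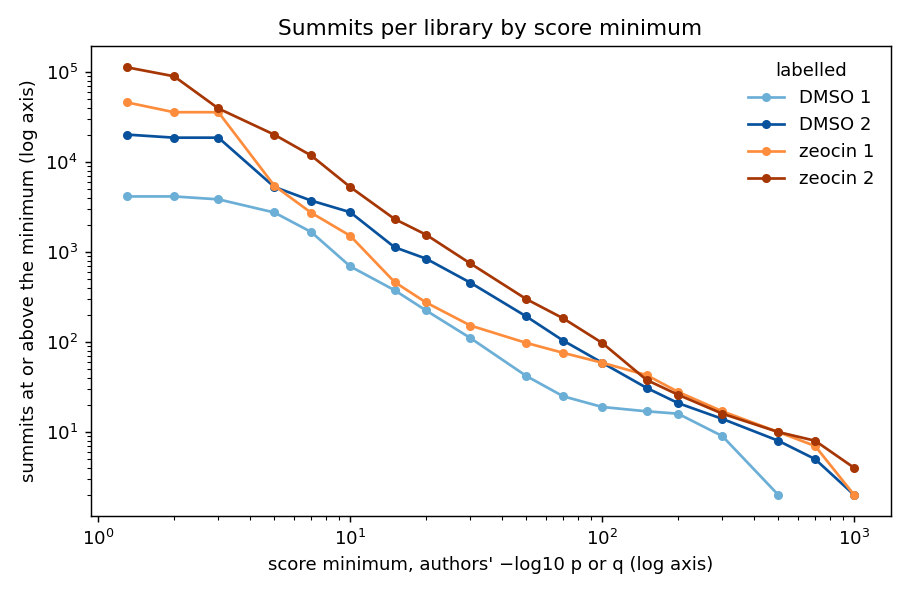
Summits at or above a score minimum in each of the 4 libraries, both axes logarithmic; the score is the authors' −log10 of a p or q value. Zeocin 1 lies above DMSO 2 at low scores (46386 against 20328 summits in the full lists), the lines meet near a score of 5 (5494 against 5322), DMSO 2 lies above from 7 to 70, both have 59 at 100, and zeocin 1 lies slightly above again from 150 to 700. A stretch of chromosome 8 described below adds summits with scores up to 336 to the zeocin 1 line and none to that of DMSO 2.

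The same place had the highest score in all 4 lists. In every library the highest score lay on the unplaced scaffold chrUn_gl000220, between 117735 and 118019, from 5658 to 5742 bp past the end of the annotated 5.8S ribosomal RNA gene RNA5-8SN2 (112025 to 112177 on that scaffold). The next highest in every library lay on mitochondrial DNA, but at different places: at position 1153 in DMSO 1, 1289 in DMSO 2, 1883 in zeocin 1 and 2144 in zeocin 2. Other leading regions shared by all 4 libraries were chromosome 21, 9826966 to 9827171 and 9825897 to 9826222, chromosome 1, 91852848 to 91853050, and chromosome 6, 52860465 to 52860670. Of 154146 regions made from the 4 lists, 934 were called in all 4 libraries, against a mean of 6.82 when summits were displaced by 10 to 50 kb. This count ranged from 62 with strong summits alone, 408 in lists of equal length, 430 with a score minimum of 5 and 559 with summits within 100 bp, to 1688 and 1981 with 250 and 500 bp on either side of a summit and 4184 without DMSO 1. Across 23 chromosomes, the number of summits followed the number of protein-coding genes with Pearson's r from 0.905 (DMSO 1) to 0.927 (DMSO 2) and Spearman's rho from 0.875 (DMSO 1) to 0.937 (zeocin 2). Each of these 4 relations had a permutation p of 1e-05, the smallest 100000 permutations give, also after Benjamini-Hochberg adjustment, and r stayed between 0.809 and 0.909 without chromosomes 1 and 19. Longer chromosomes hold more of both, chromosome length was not taken into account, and chromosomes are not independent replicates.

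Regions called in both libraries labelled zeocin and in neither labelled DMSO numbered 9619, against a mean of 3649.5 for displaced summits. Few were strong in both libraries (37), and 39.9% had only the 2 lowest scores in both. With the 4171 strongest summits of each library, 182 regions were zeocin-only and 231 DMSO-only, while a score minimum of 5 left 762 and 141, and strong summits alone 53 and 6. Of those 37, 34 lay in a single stretch of chromosome 8, from 133880328 to 134146920, and 9 of the 10 leading regions of this pattern were there too. The remaining one was on chrUn_gl000220, from 144162 to 144418, with a DMSO 2 summit 287 bp away. For comparison, 6225 regions were called in DMSO 2 and zeocin 2 alone (displaced mean 1664.6), and 505 in DMSO 1 and zeocin 1 alone (displaced mean 213.7).

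The chromosome 8 stretch matched the exons of TG, the gene of thyroglobulin, the protein from which the thyroid makes its hormones. Zeocin 1 had 50 summits there, 47 of them strong, and zeocin 2 had 44, of which 34 were strong, while DMSO 1 and DMSO 2 had 0. The stretch held 17.0% of all strong summits of zeocin 1 and 1.79% of those of zeocin 2. Its highest score was 336 in zeocin 1, at 134042066, and 120 in zeocin 2, at 134145708. An annotation of hg19 was not used here. The name comes from spacing: distances between summits were compared with distances between exons of 13571 genes of GENCODE 29. Each gene was compared only with summits on its own chromosome and under offsets of up to 3 Mb. Only genes near the stretch could therefore match it in this form of the search. Under a single offset, 48 of the 53 merged exons of TG held a summit of zeocin 1 and 41 held one of zeocin 2, and the highest count in 20 draws of displaced summits was 10 in each library. This search was devised after the stretch had been seen.

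**Figure D2:**
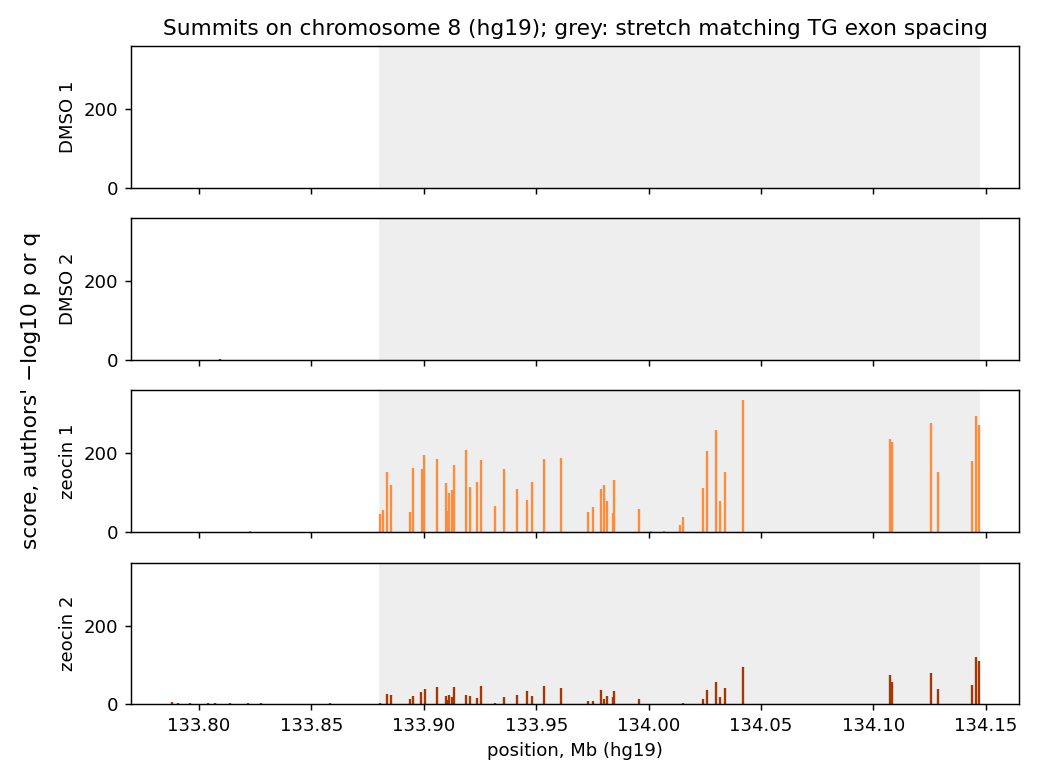
Summits around the chromosome 8 stretch (hg19 position in Mb) in the 4 libraries, drawn at the height of the authors' score; the grey area is the stretch that matched the exon spacing of TG. Zeocin 1 has 50 summits in the grey area and zeocin 2 has 44, and both DMSO libraries have 0.

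Regions called in both libraries labelled DMSO and in neither labelled zeocin numbered 250 in the full lists, against a displaced mean of 122, and 6 were strong in both. The first was on mitochondrial DNA, from 1053 to 1389. Mitochondrial DNA also held the score of rank 2 in each zeocin library, at 1883 in zeocin 1 and 2144 in zeocin 2, so only the place differed. The next was on chrUn_gl000220, from 153323 to 153654. Further ones were on chromosome 12, 120636483 to 120636683 and 54679778 to 54680036, chromosome 16, 29821667 to 29821893, chromosome 1, 245015371 to 245015585 and 245012360 to 245012649, and chromosome 11, 65190366 to 65190651. Over the 10 leading regions, the nearest zeocin summit lay from 271 to 7197 bp away: 594 bp from the mitochondrial region, 590 bp from that on the scaffold, 572 and 1228 bp from those on chromosome 12, 1175 and 1747 bp from those on chromosome 1, and 271 bp from those on chromosomes 16 and 11. With 500 bp on either side of a summit in place of 100 bp, 22 such regions were left, while leaving out 1 library gave 571 to 7364.

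**Figure D3:**
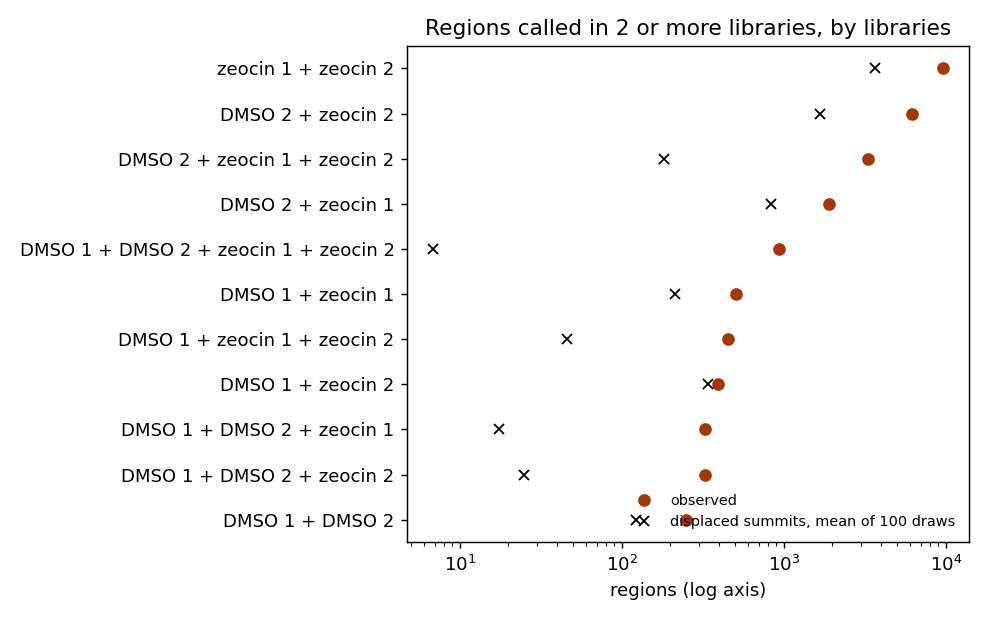
Regions called in 2 or more libraries, by the libraries that called them (logarithmic axis); dots are the observed numbers and crosses the mean of 100 draws with displaced summits. Zeocin 1 with zeocin 2 has the most regions (9619) and DMSO 1 with DMSO 2 the fewest (250) in the full lists, an order that turns in lists of equal length (182 against 231) but not with a score minimum of 5 (762 against 141).

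On average, libraries with the same label did not share more summits than libraries with different labels, with means of 23.5% and 28.8% in lists of equal length. In lists cut to the 4171 strongest summits, DMSO 1 and DMSO 2 shared 25.9% (95% Wilson interval 24.6 to 27.3) and zeocin 1 and zeocin 2 shared 21.1% (19.9 to 22.4). DMSO 2 and zeocin 2 shared 44.0% (42.5 to 45.5), the most of the 6 pairs. The other pairs with different labels shared 25.4% (DMSO 1 and zeocin 1), 24.8% (DMSO 1 and zeocin 2) and 21.0% (DMSO 2 and zeocin 1). Displaced summits gave 0.635% to 0.819%. Lists of equal length are not equally strong. The 4171 summits are all of DMSO 1, and 33.7% of them had the 2 lowest scores. Zeocin 2, by contrast, had 5311 summits with a score of 10 or more. DMSO 2 and zeocin 2 also had the most strong summits (848 and 1904, against 170 in DMSO 1 and 276 in zeocin 1). Strong summits were found again more often, so strength was not separated from label or library here. In the full lists, pairs with the same label shared a mean of 35.9% and pairs with different labels 44.8%, a difference of -8.90 percentage points. These lists differ in length. Set against displaced summits, DMSO 1 and DMSO 2 had the highest ratio, 14.5, but the displaced share itself rises with the length of the searched list. In lists of equal length this ratio was 66.1 for DMSO 2 with zeocin 2 and 39.8 for DMSO 1 with DMSO 2.

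**Figure D4:**
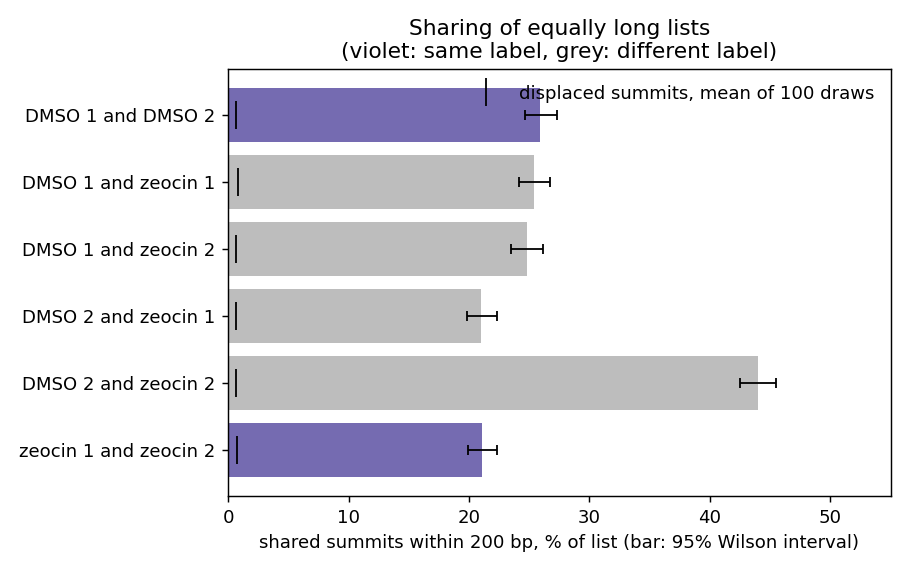
Share of summits within 200 bp of a summit of the other library, for the 4171 strongest summits of each list; error bars are 95% Wilson intervals and black marks the mean of displaced summits. DMSO 2 and zeocin 2 share 44.0%, and the other 5 pairs lie between 21.0% and 25.9%. The lists are of equal length but not of equal strength, since the 4171 are all the summits of DMSO 1.

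Strong summits were found again more often than weak ones. Of the summits of zeocin 1 at the 2 lowest scores, 26.1% (95% Wilson interval 25.6 to 26.5) had a summit of zeocin 2 within 200 bp, against 65.6% (59.8 to 70.9) of its strong summits. The TG stretch raised the latter share: it held 47 of the 276 strong summits of zeocin 1. Their median distance to a zeocin 2 summit was 5 bp, against 108 bp for the other strong summits. In DMSO 1 the shares found in DMSO 2 were 33.3% (30.9 to 35.8) and 75.3% (68.3 to 81.2). In zeocin 2, the much longer list, the summits of DMSO 1 at the 2 lowest scores were found in 41.8% (39.3 to 44.4) and its strong summits in 65.9% (58.5 to 72.6), and the strong summits of DMSO 2 in 77.0% (74.1 to 79.7). These intervals cover counting error only.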

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

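Wider windows, strong summits alone, the treatment of the peak names and the removal of the TG stretch were chosen after seeing the data. With the treatment of the peak names, the log2 ratios of summit number and covered length reversed to -2.98, zeocin-only regions became 250 and DMSO-only regions 9619. Otherwise both ratios kept their direction, from 1.84 to 4.12 with each library left out, and no test could pass 0.05. A score minimum of 5 left 762 zeocin-only, 141 DMSO-only and 430 shared regions. Equal list length left 182 zeocin-only and 408 shared regions, fewer zeocin-only than the 231 DMSO-only ones; summit number and covered length are then fixed and were not compared. Strong summits alone left 53, 6 and 62. Summits within 100 bp gave 6070 zeocin-only and 559 shared regions. With 250 bp on either side, DMSO-only regions numbered 109 and shared ones 1688, and with 500 bp 22 and 1981. Leaving out each library gave 10044 to 102502 zeocin-only, 571 to 7364 DMSO-only and 1212 to 4184 shared regions. Fewer lists must then hold or lack a summit. Without the TG stretch 9573 zeocin-only regions were left. The replicate block gave a log2 ratio of 2.98 with an exact sign-flip p of 0.5, the smallest it allows; nothing in the labels says that the numbers pair the libraries. Causes of these changes were not tested. Alternatives for genes, gene lists, exons and the DRACH motif were not run.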

Other observations

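Scaffolds whose sequence is the same in both builds allow a few more names. All summits on one of them fell in MAFIP, which overlaps AC145212.1: 7 in DMSO 1, 9 in DMSO 2, 29 in zeocin 1 and 38 in zeocin 2. The ribosomal scaffold chrUn_gl000220 had 19 summits in each DMSO library and 24 in each zeocin library. The full lists hold 4171 summits in DMSO 1, 20328 in DMSO 2, 46386 in zeocin 1 and 113876 in zeocin 2. Neither scaffold therefore shows a rise under the zeocin label beyond that of the lists. The 6 chromosomes densest in coding genes (19, 17, 11, 16, 22 and 20) held 31.5% ± 2.57 (SD, n = 2) of DMSO summits and 27.2% ± 2.23 (SD, n = 2) of zeocin summits in the full lists (exact permutation p = 0.333), but 33.0% and 34.1% in lists of equal length (exact permutation p = 1).

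All tests below were chosen after the results were seen, except that of the 200 strongest summits.

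The TG exons called in both zeocin libraries and no DMSO library may be RNA or cDNA from outside the culture, or a change of this transcript with the treatment. These cannot be told apart, since the treatment and any foreign RNA follow the same groups: 48 TG exons were held in zeocin 1 and 41 in zeocin 2. With a minimum of 2 levels, the search gave 48 TG exons in zeocin 1 and 44 in zeocin 2. That list holds every summit of the main list, so these counts could not fall. Over all chromosomes, 47 of the 47 strong summits of zeocin 1 in the stretch fell in TG exons, against 36 in those of TTN, the next gene. TTN has 368 merged exons over 39.0% of its length, and TG has 53 over 4.15%. The stretch was bounded by summits that matched TG, so this is not a separate check of the name.

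The background in the caller's model, read from the spacing of the scores, was not higher in zeocin 1 (0.960 of the lower DMSO background), so a higher background does not account for its larger number of summits. In zeocin 2 it was 1.79 times the higher DMSO background. By itself a higher background lowers the score of a given coverage, so it could add summits only where it stands for deeper sequencing. Whether it does depends on the control of the calls, which is not given in the sources used here. Read coverage itself is unknown in all 4 libraries and stays open. Weak summits near the calling floor could make up the excess of zeocin 1 over DMSO 2. Zeocin 1 had 0.325 (95% interval 0.284 to 0.373, counting error only) times as many strong summits as DMSO 2. Over DMSO 1 the ratio was 1.62, but the lowest scores differ (2.70 in DMSO 1 and 1.71 in zeocin 1), so strong summits start at unlike scores. With a score of 20 or more, zeocin 1 had 276 summits and DMSO 1 had 225. The TG stretch held 47 of the 276 strong summits of zeocin 1. Whether part of the excess over DMSO 1 remained among strong summits is therefore not decided. Exchanged labels cannot be told apart from a treatment effect: the peak names give the other treatment in 4 of 4 lists, and nothing else in the lists reports the treatment.

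DMSO 2 and zeocin 2 shared more than any other pair also among the 200 strongest summits. The share was 67.5% (95% Wilson interval 60.7 to 73.6) against 47.5% for the next pair. All of these summits had scores of 20 or more, so the lead was not limited to the lowest scores. The lists were not equally strong, however. The 200 include all 170 strong summits of DMSO 1 but only part of the 848 of DMSO 2 and 1904 of zeocin 2. Strong summits were found again more often, so strength was not separated from the pair. Whether chance near the floor sets this pair apart is therefore not decided. A batch shared by libraries of the same number could make DMSO 2 and zeocin 2 share more. DMSO 1 shared only 0.623 percentage points more with zeocin 1 than with zeocin 2 in lists of equal length. Among the 200 strongest it shared 39.0% with zeocin 1 and 42.5% with zeocin 2, with overlapping intervals, which does not decide the question. All 47 strong summits of zeocin 1 in the TG stretch are among its 200 strongest. DMSO 1 has 0 summits there, so these places in the zeocin 1 list could not be shared with it. The replicate number in the peak names is 1 for both zeocin lists, so the numbers themselves are in doubt. No biological explanation was tested, since the pair has different treatments.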
